A study of Homo sapiens with 2 samples.

How the data were processed

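Small RNA libraries were made from total RNA of D407, an established human retinal pigment epithelial (RPE) cell line, grown with or without clusterin, a secreted glycoprotein that acts as an extracellular chaperone. Per the labels' protocols, small RNA libraries followed the Illumina TruSeq small RNA protocol, with adaptor ligation and reverse transcription, and were sequenced on a HiSeq instrument. There was 1 library from clusterin-treated cells and 1 from control cells. The labels describe a viability assay over 0 to 10 µg/ml clusterin, but they do not say which concentration or duration was used for the sequenced cells. The study's mRNA libraries were not analysed here.

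Each deposited table lists 2588 mature human miRNA names with a raw read count and a normalized value. The deposited count column, made by the authors, holds whole numbers. In both libraries the lowest count above 0 was 10, so a miRNA listed at 0 is taken to have had 9 reads or fewer. The deposited normalized column is in RPM (reads scaled to a fixed library total). Dividing count by RPM, over miRNAs with more than 1000 reads, gave 1 constant per library, 13393799 for clusterin and 13233217 for control, so the authors scaled to a total larger than the reads of the listed miRNAs. What that total counts is not given in the sources used here. The submitters' processing notes name TopHat and Cufflinks without a role or version. The miRNA aligner, the treatment of reads that match several miRNAs, the miRBase release and the genome build are not given in the sources used here. Near-identical miRNAs can therefore share reads, and values for them are uncertain.

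The clusterin library held 4491744 miRNA reads and the control library 5437696. Counts were scaled to RPM of all listed miRNA reads in the library, which is the RPM meant in the results unless the authors' RPM is named, and the log2 ratio of clusterin over control was taken per miRNA. Each ratio has a 95% interval from the exact (Clopper-Pearson) binomial interval of the clusterin count given the sum of both counts. All intervals and shares cover counting error only. Reads carry no molecular identifiers and are not independent molecules, and with 1 library per group there is no replicate check of any difference. No p-value was computed.

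The main settings below were chosen before the data were examined. A miRNA was listed as at least 2-fold higher or lower when its ratio was at least 2 or at most 0.5, its interval excluded 1 and both libraries together held at least 100 reads. A pseudocount of 0.5 read replaced counts of 0 only. The named miRNAs were the 12 highest and 12 lowest listed miRNAs by the interval bound nearest to no change, the 10 most abundant, and up to 4 of the most abundant members of each of 16 fixed lists. The lists covered let-7/miR-98, the miR-17-92 cluster with its paralogs, RPE-enriched, photoreceptor and neuronal, p53-regulated and growth-arrest, inflammation-responsive, epithelial miR-200/205, mesenchymal, miR-29/30, hypoxia and angiogenesis, miR-125/99/100, blood and serum, muscle, pluripotency, and imprinted 14q32 miRNAs. The last list held entries that can collect fragments of rRNA, tRNA or other RNA, as a sign of RNA quality. For lists with at least 3 members holding 10 reads or more, the median log2 ratio was placed among 10000 random lists matched on mean level, each member being replaced by a miRNA within 15 ranks. These percentiles describe this pair of libraries.

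Scalings tried beside the main one were the trimmed mean of M values (TMM, edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), RPM without the 5 most abundant miRNAs, and the authors' RPM. Only the scaling functions of those packages were used. The main scaling placed the median log2 ratio of the 318 miRNAs with at least 100 reads at 0.14, and the others moved that median by -0.14 to -0.29. Changes are therefore also given relative to the median. Other alternatives changed the read floor, the size of change, the interval rule and the pseudocount. For the members counted above or below the median of all miRNAs, 9 reads stood in place of a listed 0, a choice also made after the data had been seen. Taking entries listed at 0 as 9 reads, using the authors' RPM and removing a GC trend were added after the data had been seen. Detection was compared after thinning the control library to the clusterin depth in 100 draws.

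Hairpin genes were matched by symbol to GENCODE release 29 (GRCh38), which gave positions and sequences. Because the tables carry no coordinates, these describe the reference annotation. GC content was taken from the side of the hairpin that holds the named arm, or from the whole hairpin where the name gives no arm, and averaged over copies. It was available for 317 of the 318 miRNAs. The calling procedure was tested on simulated data. Counts for 525 miRNAs were drawn from the real means and library sizes of the clusterin against control comparison, with 200 miRNAs changed. At simulated 3-fold changes 100% of the miRNAs at the floor were recovered (21 higher, 13 lower), none of the 186 unchanged miRNAs was called, and 93.8% of intervals held the true value. At simulated 1.5-fold changes, which lie under the 2-fold rule, 0 of 14 higher and 0 of 16 lower were recovered. No change between 1.5-fold and 3-fold was simulated, so recovery near the 2-fold line was not measured. The draws held counting error only, so they do not measure false calls from differences between cultures or library preparations. Analyses used Python 3.11.15, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9.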

Results

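Small RNA was sequenced from D407 retinal pigment epithelial cells treated with clusterin and from untreated control cells, with 1 library per group. The comparison asks which miRNAs differ in level when this cell line is exposed to clusterin. The listed miRNAs held 4491744 reads in the clusterin library and 5437696 in the control library. In the clusterin library 488 of the 2588 miRNA names had reads, and in the control library 500 did. After the control library was thinned to the clusterin depth, 472 miRNAs had at least 10 reads, against 488 in the clusterin library. Reads were found in both libraries for 463 miRNAs. The 25 seen only with clusterin had at most 20 reads each, and the 37 seen only in the control had at most 22.

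The D407 miRNA population was dominated by miR-21-5p, a widely expressed miRNA that is abundant in proliferating cells, and its share was smaller with clusterin. miR-21-5p made up 52.96% of miRNA reads in the clusterin library (95% Clopper-Pearson interval 52.92 to 53.01) and 57.02% in the control library (56.98 to 57.06). The 10 most abundant miRNAs together held 73.7% and 77.2% of reads. After miR-21-5p came miR-30a-5p, with 50558 RPM (reads scaled to the miRNA reads of the library) in the clusterin library and 49697 in the control library. miR-100-5p stood at 31930 and 34651 RPM, a ratio of 0.92 (95% counting interval 0.92 to 0.93). let-7a-5p, of the differentiation-associated let-7 family, was at 26689 against 22808, a ratio of 1.17 (1.16 to 1.18). The ratio of let-7f-5p lay between 0.99 and 1.01 under the main scaling, but below no change by more than counting error under the 4 others. The ratios of the other members of the 10 most abundant were 1.09 for miR-27a-3p, 1.06 for miR-92a-3p, 0.98 for miR-27b-3p, 1.10 for miR-10a-5p and 1.06 for miR-24-3p. Of these 10 miRNAs, miR-21-5p, miR-100-5p and miR-27b-3p were lower with clusterin under the main scaling, by more than counting error. The 4 other scalings shift every log2 ratio downward, so these miRNAs are lower there too by construction. The direction of miR-30a-5p, let-7a-5p, let-7f-5p, miR-27a-3p, miR-92a-3p, miR-10a-5p and miR-24-3p differed between scalings.

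Most miRNAs were at similar levels in both libraries, and 4 were at least 2-fold higher with clusterin. Among the 318 miRNAs with at least 100 reads, 280 (88.1%) differed by less than 1.5-fold. miR-451a, an erythroid miRNA whose maturation bypasses Dicer, stood furthest apart at 78.1 RPM with clusterin and 14.9 without, a ratio of 5.25 (95% counting interval 4.11 to 6.77). miR-19b-3p, a member of the growth-promoting miR-17-92 cluster, was at 410 against 169 RPM, a ratio of 2.43 (2.24 to 2.63). The less abundant miR-4443 had a ratio of 2.31 (1.65 to 3.27) and miR-4483 one of 2.17 (1.79 to 2.63). No miRNA was 2-fold lower. The lowest ratio, named after its value was seen, was 0.59 for miR-1275 (0.42 to 0.83). Under the authors' RPM scaling, miR-451a was the 1 miRNA at least 2-fold higher, and miR-1275, miR-7704 and miR-7975 were at least 2-fold lower. There miR-19b-3p and miR-4443 lay just under 2-fold, at log2 ratios of 0.99 and 0.91. miR-4483 was under 2-fold in the 4 scalings other than the main one, at log2 ratios of 0.82 to 0.98. The intervals lay above no change for 139 miRNAs and below it for 40 under the main scaling, and for 49 and 40 under all 5 scalings. Since the 4 other scalings only shift all ratios downward, the 40 could not become fewer, and their agreement is no added check. These differences have no replicate check. The spread of log2 ratios among 153 miRNAs with at least 1000 reads was 0.32 (SD across miRNAs), against a median counting error of 0.037. With 1 library per group, that spread can also hold differences between cultures or library preparations.

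**Figure D1:**
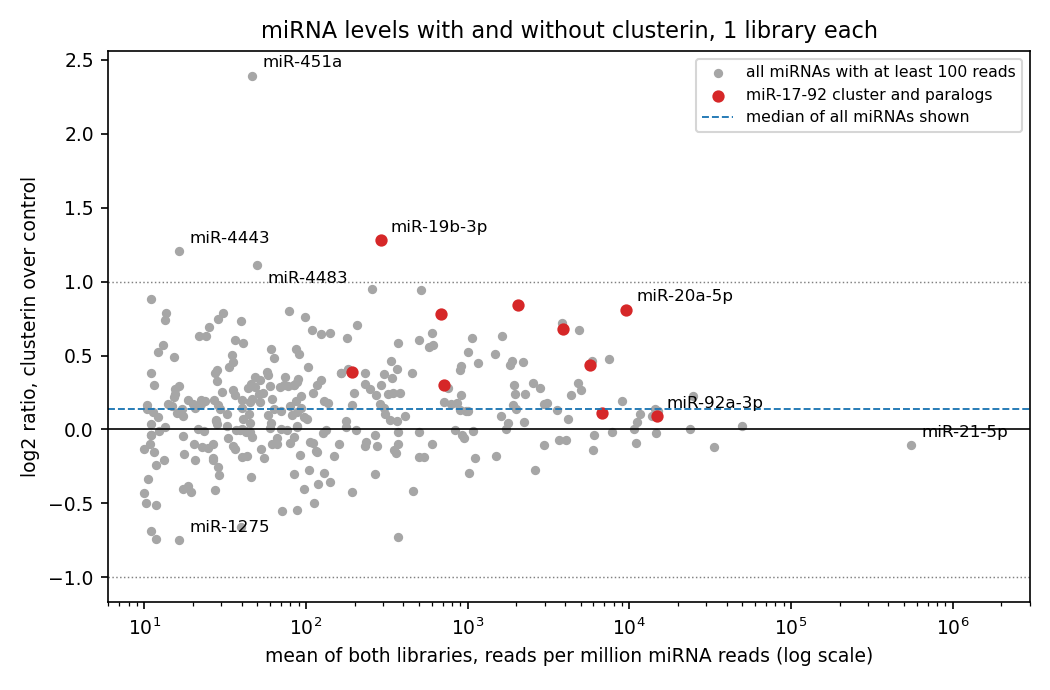
Each point is 1 of 318 miRNAs with at least 100 reads in both libraries together. The horizontal axis gives the mean of both libraries in RPM on a log scale, and the vertical axis the log2 ratio of clusterin over control, 1 library each. Dotted lines mark 2-fold differences and the dashed line the median of 0.14; miR-451a, miR-19b-3p, miR-4443 and miR-4483 lie above the upper dotted line, and miR-17-92 members are red.

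In GENCODE release 29 (GRCh38), the hairpin of miR-451a lies on chromosome 17 from 28861369 to 28861440 on the minus strand. It overlaps an exon of the lincRNA AC024267.1, and the hairpin of miR-451b on the opposite strand. miR-19b-3p has a pair of hairpin copies. MIR19B1 lies on chromosome 13 from 91351192 to 91351278, within an exon of the miR-17-92 host gene MIR17HG. MIR19B2 lies on chromosome X from 134169671 to 134169766, within an exon of AC002407.1. The miR-4443 hairpin lies on chromosome 3 from 48196564 to 48196616 and overlaps no other annotated gene. The miR-4483 hairpin lies on chromosome 10 from 113777993 to 113778054, opposite an intron of the protein-coding gene PLEKHS1.

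The miR-17-92 cluster and its paralogs, a set of miRNAs known to promote proliferation, stood higher in the clusterin library as a group. Of 13 members, 10 had reads, and 8 of these lay above the median of all miRNAs by more than their counting intervals while 2 lay below. The list's median was 0.42 above the median of all miRNAs on the log2 scale, at the 99.99th percentile of matched random lists. miR-20a-5p stood at 12152 RPM with clusterin and 6933 without, a ratio of 1.75 (1.73 to 1.78). The ratios were 1.79 for miR-106a-5p, 1.72 for miR-19a-3p, 1.60 for miR-17-5p, 1.35 for miR-93-5p, 1.31 for miR-18a-5p and 1.23 for miR-106b-5p. miR-92a-3p and miR-25-3p, which share a seed sequence, lay 0.05 and 0.02 below the median, at ratios of 1.06 (1.05 to 1.08) and 1.08 (1.07 to 1.10), and the sign of both differed between scalings. miR-18b-5p, miR-20b-5p and miR-363-3p were listed at 0 in both libraries. miR-17-5p, miR-20a-5p and miR-106a-5p are near-identical, so reads can be shared among them. With any 1 member left out, the percentile stayed at 98.78 or higher and the median at 0.30 to 0.54. Leaving out 1 member keeps its near-identical or clustered relatives, and the random lists draw members independently, so neither covers members that vary together.

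Other growth and stress lists did not stand apart from matched random lists. Of 9 let-7 and miR-98 members, 5 lay above the median of all miRNAs and 2 below, with a list median of 0.05 relative to it at the 83.7th percentile. let-7g-5p had a ratio of 1.14 and let-7i-5p one of 1.07. In the p53-regulated and growth-arrest list, 4 of 6 members with reads lay above and 1 below (median 0.20, 94.2nd percentile). There miR-16-5p had a ratio of 1.35 (1.31 to 1.39), miR-194-5p 1.43, miR-15a-5p 1.26 and miR-192-5p 0.93. In the miR-29 and miR-30 families, 5 of 8 lay above and 2 below (median 0.22, 94.2nd percentile). miR-30c-5p had a ratio of 1.39 (1.37 to 1.41), miR-29a-3p 1.21 and miR-30d-5p 1.04. The highest of the 8, named after its value was seen, was miR-29b-3p at 1.93, with 1510 and 948 reads. miR-29c-3p had 1.69, but at 39 and 28 reads its interval included the median of all miRNAs. In the inflammation-responsive list, 1 of 4 lay above and 2 below (median -0.01, 50.9th percentile). There miR-146b-5p had a ratio of 1.28 (1.10 to 1.48), miR-146a-5p 1.49 (1.03 to 2.15) and miR-132-3p 0.92, with an interval that included no change under the main scaling but lay below it under the 4 others. The interval of miR-146a-5p lay above no change in 1 of 5 scalings and that of miR-146b-5p in 2, and miR-155-5p was listed at 0. In the hypoxia and angiogenesis list, 5 of 11 lay above and 4 below (median -0.01, 52.1st percentile), and miR-23a-3p had a ratio of 1.20 (1.18 to 1.23). Members named after their values were seen went both ways. miR-222-3p had a ratio of 1.64 and miR-210-3p 1.47, but the other arm, miR-210-5p, had 0.62 with 38 and 74 reads. In the miR-125 and miR-99/100 families, 2 of 5 lay above and 3 below (median -0.06, 23.6th percentile). Their ratios were 1.13 for miR-125b-5p and 1.05 for miR-99b-5p, and the interval of miR-99a-5p ran from 0.99 to 1.01 under the main scaling but lay below no change under the 4 others. The signs of let-7g-5p, let-7i-5p, miR-29a-3p, miR-30d-5p, miR-23a-3p, miR-125b-5p, miR-99a-5p and miR-99b-5p differed between scalings.

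Of the 4 miRNAs enriched in retinal pigment epithelium, 1 had reads. miR-204-5p, miR-204-3p and miR-211-5p, which are enriched in native retinal pigment epithelium, were listed at 0, that is at no more than 9 reads of a library. miR-184 had 30.9 RPM with clusterin and 28.1 without, a ratio of 1.10 (0.87 to 1.39). The photoreceptor and neuronal list included the miR-183/96/182 cluster, with ratios of 1.30 for miR-96-5p and 1.13 for miR-182-5p. The interval of miR-183-5p was 0.97 to 1.03, and it lay below no change under the 4 other scalings. miR-128-3p had a ratio of 1.43 (1.38 to 1.47), and neuronal miR-124-3p was listed at 0. In this list 4 of 6 members with reads lay above the median of all miRNAs and 1 below (median 0.31, 91.2nd percentile). In the mesenchymal list 1 of 7 lay above and none below (median 0.05, 64.6th percentile), with ratios of 1.12 for miR-143-3p, 1.30 for miR-10b-5p and 1.05 for miR-199a-3p. The epithelial miR-200 members were low and 0 of 3 lay above or below (median 0.15, 71.4th percentile). miR-200c-3p had 238 and 236 reads (ratio 1.22, 1.02 to 1.47), and miR-200b-3p and miR-200a-3p had at most 33 reads per library. None of the 10 pluripotency miRNAs had reads, and of 26 miRNAs of the imprinted 14q32 cluster 1 did, miR-127-3p, with 16 and 13 reads. The signs of miR-184, miR-183-5p, miR-182-5p, miR-143-3p, miR-199a-3p, miR-200b-3p and miR-200c-3p differed between scalings.

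Among miRNAs of other cell types, miR-451a lay above miR-486-5p and miR-122-5p, the other blood and serum miRNAs with reads in both libraries. miR-486-5p, also abundant in red cells, had 37 and 39 reads, a ratio of 1.15 (0.71 to 1.85). The liver and serum miRNA miR-122-5p had 12 and 16 reads, a ratio of 0.91 (0.39 to 2.05). miR-150-5p had 10 reads with clusterin and was listed at 0 in the control, which does not place it relative to miR-451a, while miR-144-3p, miR-142-5p, miR-142-3p and miR-223-3p were listed at 0 in both libraries. The list's median was 1.16 above that of all miRNAs (99.9th percentile) with a pseudocount for miR-150-5p, but 0.18 (76.1st percentile) with 9 reads in its place. Of the muscle miRNAs, miR-1-3p had a ratio of 0.80 (0.66 to 0.97), miR-133a-3p 0.79 (0.42 to 1.46) and miR-499a-5p 1.21 (0.55 to 2.66), with 1 of 3 members below the median of all miRNAs (list median -0.46, 3.89th percentile). Of the 13 entries with reads that can collect fragments of other RNA, 2 lay above and 3 below the median. Their median was -0.39 (0.75th percentile), or -0.23 (4.92nd percentile) with 9 reads in place of 0. Among them, miR-7704 had a ratio of 0.60 (0.40 to 0.88), miR-1260b 0.94 (0.80 to 1.09), miR-1246 1.19 (1.11 to 1.27) and miR-1291 1.73 (1.20 to 2.49). The signs of miR-486-5p, miR-499a-5p and miR-1246 differed between scalings. With 13 lists placed, 0.65 would lie outside the central 95% by chance if the members of a list varied independently.

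**Figure D2:**
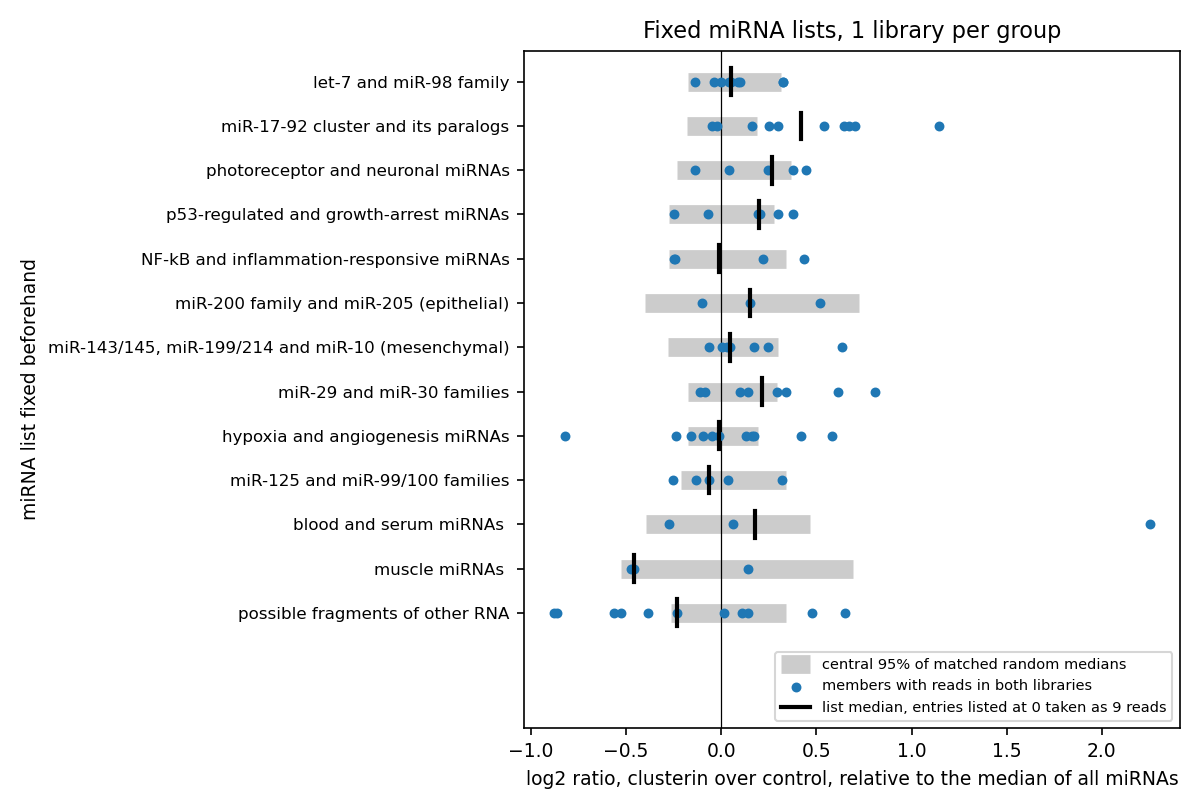
Each row is 1 of the 13 fixed lists with at least 3 members; the horizontal axis gives the log2 ratio of clusterin over control relative to the median of all miRNAs. Points are members with reads in both libraries, black bars the list medians with entries listed at 0 taken as 9 reads, and grey bands the central 95% of medians of matched random lists. The miR-17-92 median of 0.42 lies to the right of its band, and the other 12 bars lie within theirs.

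The log2 ratio also varied with base composition. Across 317 miRNAs, which are not independent replicates, it declined with the GC content of the arm side of the hairpin (Pearson r = -0.37, Spearman rho = -0.39), by 0.12 per 10 percentage points. Among the 79 miRNAs with the lowest GC content the median stood 0.13 above that of all miRNAs, and among the 80 with the highest it stood at -0.15 relative to it. With the linear trend removed, the relative median of the miR-17-92 list was 0.38 (99.97th percentile) and that of the entries that can hold other RNA was -0.15 (12.4th percentile). miR-4483, at a ratio of 2.17 before, was then at 1.86, just under 2-fold. The pair of arms of 1 hairpin, cut from the same precursor, had ratios whose Pearson correlation varied with the read floor. Across 92 hairpins with at least 50 reads per arm, Pearson r was 0.15 (95% interval by Fisher transformation -0.05 to 0.35) and Spearman rho 0.20. Pearson r was 0.38 (0.07 to 0.62) and rho 0.39 across 38 hairpins with at least 500 reads per arm. Across 124 with at least 10, r was 0.43 (0.27 to 0.56) while rho was again 0.20. At that floor the pseudocount can set the ratios of both arms of a hairpin, and what it adds to r was not tested. Hairpins are not independent replicates.

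**Figure D3:**
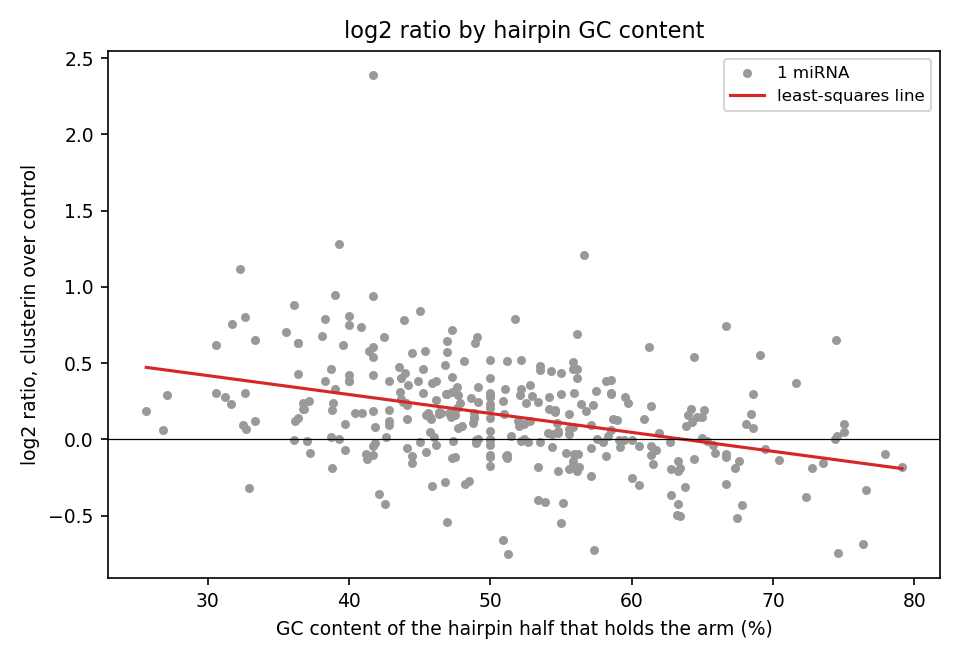
Each point is 1 of 317 miRNAs with at least 100 reads. The horizontal axis gives the GC content in percent of the arm side of the hairpin that holds the miRNA, the vertical axis the log2 ratio of clusterin over control, and the red line is the least-squares fit, which declines by 0.12 per 10 percentage points of GC.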

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

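The tests in this part were all chosen after the values had been seen. The deposited RPM column, which enters the comparisons only as an alternative scaling, carries a signal of its own. It implies that 66.5% of the authors' library total lay outside the listed miRNAs in the clusterin library, above 58.9% in the control library. The listed miRNAs held 33.54% (95% Clopper-Pearson interval 33.51 to 33.56) and 41.09% (41.06 to 41.12).

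A smaller share of miR-21-5p makes up most of this difference, but is not enough to account for all of it. The other listed miRNAs held 15.8% and 17.7% of the total, a difference of -1.89 percentage points with intervals that do not overlap. A candidate explanation is more fragments of other RNA in the clusterin library. Of the entries that can collect such fragments, 11 had reads in both libraries. Their median log2 ratio was -0.39 in the authors' RPM, with 9 of 11 lower. That scaling shifts every ratio by -0.29 from the main one, and the median of the 318 miRNAs with at least 100 reads was -0.16 there. The count of lower entries therefore partly reflects the scaling. Since most such reads would not be counted under any miRNA name, and 2 entries went the other way, the fragment explanation stays open. A lower miRNA content of clusterin-treated cells also stays open, as untested: with 1 library per group it cannot be told apart from a difference in library preparation.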

How the results depend on the processing

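No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of the 4 miRNAs at least 2-fold higher, miR-451a, miR-19b-3p and miR-4443 remained under TMM, median-of-ratios and scaling without the 5 most abundant miRNAs. Under the authors' RPM the count was 1 higher (miR-451a) and 3 lower, since that scaling moves the median log2 ratio by -0.29. With no read floor, 33 were higher and 38 lower, of which 25 and 37 were listed at 0 in the other library. With 9 reads in place of 0, no floor gave 9 higher and 1 lower. A floor of 20 reads gave 9 and 2, and a floor of 1000 reads gave 1 higher (miR-19b-3p). Counting changes of 1.5-fold gave 33 higher and 5 lower, changes of 4-fold 1 higher (miR-451a), and intervals that exclude a 2-fold change 2 higher (miR-451a and miR-19b-3p). The pseudocount moved no call, as no miRNA above the floor was listed at 0. Of the fixed lists, 2 lay above and 1 below the central 95% of matched random lists. With 9 reads in place of 0 these became 1 and 0, with members of at least 100 reads 1 and 0, and with list means or the GC trend removed 0 lay below. For the entries that can hold other RNA, the median log2 ratio was here not taken relative to all miRNAs. It changed sign from -0.25 to 0.076 with members of at least 100 reads, still below the 0.14 of all miRNAs. The value then rests on miR-1291, miR-1246, miR-1260b and miR-7704 alone, at 0.79, 0.25, -0.10 and -0.74. The Pearson correlation of arms was 0.38 at 500 reads per arm and 0.43 at 10, where Spearman rho was 0.20 as at 50 reads. Both arms of miR-548a and miR-548ap (higher) and of miR-6516 (lower) were called with no floor, but not with 9 reads in place of 0. Their ratios thus rest on the pseudocount. Such hairpins can raise the Pearson correlation at 10 reads, but it was not recomputed with 9 reads in place of 0, so the cause was not tested. Of 55 named miRNAs, 26 had a sign that differed between scalings. Depth limits the sparse miRNAs: with 40 and 81 reads, the interval of miR-7704 ran from 0.40 to 0.88.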

Other observations

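The miRNAs in this paragraph were named after their values had been seen. miR-222-3p was at 4775 against 2904 RPM, a ratio of 1.64 (95% counting interval 1.61 to 1.68), while its cluster partner miR-221-3p had a ratio of 1.24 (1.22 to 1.26) and the other arm, miR-221-5p, one of 1.33 (1.24 to 1.42). miR-224-5p had a ratio of 1.60 (1.57 to 1.63), but miR-452-5p, encoded close to it, had 1.07 (1.03 to 1.10), with a sign that differed between scalings, and the other arm, miR-224-3p, had 1.12 (0.85 to 1.48). miR-4521 had a ratio of 1.92 (1.81 to 2.04). On the lower side, miR-378a-3p, the most abundant member of a family linked to energy metabolism, had a ratio of 0.83 (0.81 to 0.85) and miR-378b one of 0.63 (0.51 to 0.78). Under the main scaling the intervals of the other arm, miR-378a-5p (0.82 to 1.22), of miR-378d (0.60 to 1.38) and of miR-378g (0.46 to 1.07) included no change, but that of miR-378g lay below it under the 4 other scalings and that of miR-378a-5p under 1. miR-181a-5p was at 0.82 (0.78 to 0.85), but miR-181b-5p at 1.10 (1.05 to 1.14) and miR-181d-5p at 1.23 (1.07 to 1.42), though the sign of miR-181b-5p differed between scalings and the interval of miR-181d-5p included no change under the 4 other scalings. Also lower were miR-744-5p at 0.75 (0.71 to 0.80) and miR-7975 at 0.60 (0.56 to 0.65). miR-675-5p and miR-675-3p, both cut from the H19 transcript, were at 0.96 (0.921 to 0.999) and 0.91 (0.85 to 0.97). miR-107 and miR-103a-3p, which are near-identical and can share reads, went apart at 1.57 (1.40 to 1.76) and 0.97 (0.96 to 0.99). The intervals of miR-222-3p, miR-224-5p, miR-4521 and miR-107 lay above no change under all 5 scalings. Those of miR-378a-3p, miR-378b, miR-181a-5p, miR-744-5p, miR-7975, both miR-675 arms and miR-103a-3p lay below it under the main scaling. They are below it under the 4 others by construction, since those shift every ratio downward. Neighbouring hairpins within 10 kb (37 pairs) differed by a median of 0.24 on the log2 scale, against 0.31 for random pairs, whose central 95% ran from 0.20 to 0.45.

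The tests in this and the next paragraph were chosen after the ratios had been seen. The miR-17-92 list stood 0.42 above the median of all miRNAs, a shift that clusterin treatment may have caused or that may be technical. A linear dependence on hairpin GC content is argued against as the whole cause: fitted on miRNAs outside the list and removed, it left the list at 0.38 and the 99.97th percentile. An equal rise of the 6 mature miRNAs of the miR-17-92 transcript is argued against, as they spanned 1.19 on the log2 scale, from miR-92a-3p to miR-19b-3p, beyond 0.68, the upper end of the central 95% for sets drawn from differences between arms; this test replaced an earlier one, on miR-92a-3p alone (-0.05 relative to the median), after its result was known. Both end members have a second hairpin copy elsewhere, so the span of the 6 does not measure the transcript alone. The 4 with 1 copy (miR-17-5p, miR-18a-5p, miR-19a-3p and miR-20a-5p) all lay above the median and spanned 0.42. That is within the 0.65 for sets of 4 drawn from differences between arms, but also at the 24.1st percentile of random sets of 4 miRNAs. miR-92a-1-5p, the 5p arm of a hairpin of the same cluster and not among those 4, had a log2 ratio of 0.26. The median of all miRNAs was 0.14. It lay 0.55 under miR-20a-5p, a wider span than that of the 4, which was not set against drawn sets. More of the transcript therefore stays open. A difference between cultures or library preparations cannot be told apart from the treatment with 1 library per group.

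The ratio of miR-451a was 5.25, and over the 5 scalings it lay between 4.28 and 5.25. Counting error does not account for it, as the lower bound of its interval was 4.11. Blood or serum RNA is a candidate source, since red cells are rich in miR-451a and the growth medium contained fetal bovine serum. Serum present alike in both cultures would not by itself give a difference between them. The 2 other blood and serum miRNAs with reads in both libraries, miR-486-5p and miR-122-5p, had a median of -0.11 relative to all miRNAs, but at 12 to 39 reads each a small addition to them would not show, and miR-150-5p, with 10 reads against a listed 0, goes in the direction of such a source but may have had up to 9 reads in the control. This source and a response of the cells both stay open.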
